A study of Homo sapiens with 4 samples.

How the data were processed

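The series holds 4 droplet single-cell RNA libraries from trophoblast cells derived from naive human pluripotent stem cells. Per the labels, the starting cells were the naive form of H9, an established human embryonic stem cell line. Naive cells resemble the early epiblast of the blastocyst and can form trophectoderm, the outer layer of the blastocyst. The libraries of days 2 and 3 (nTE_D2 and nTE_D3) came from cells on a laminin-511 fragment with A83-01, an inhibitor of the NODAL and TGF-beta receptors, at 2 uM and PD0325901, a MEK inhibitor, at 2 uM. BMP4 was added at 10 ng/ml on the first day only, and JAK inhibitor I at 1 ug/ml from day 1. Cells of both libraries were sorted for TACSTD2. The libraries of days 5 and 10 (nCT_D5 and nCT_D10) came from day-3 cells sorted for both TACSTD2 and ENPEP and recultured with A83-01 at 1 uM, CHIR99021, a GSK3 inhibitor that activates WNT signalling, at 2 uM, and EGF at 50 ng/ml.

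Libraries were made with a Chromium 3' kit of version 3.1, per the labels, and counted with Cell Ranger 5.0.1 on GRCh38, per the submitters' processing notes. The annotation used for counting is not given in the sources used here. The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization by the authors beyond the cell calling of Cell Ranger. The matrices hold 36601 features and 14164 barcodes, namely 2378, 5148, 3529 and 3109 in order of day, and these numbers equal the cell numbers that the labels state. Gene positions were taken from GENCODE release 29 on GRCh38, which has an entry for 34616 features (94.6%). All positions are 1-based and span the whole gene. The counting assigns a 3' tag to a gene and does not separate near-identical copies, so values of CGB3, PSG3, XAGE2, LGALS16, ALPG, POU5F1 and the HLA genes, which have close paralogs or pseudogenes, are uncertain to that extent. SNRPN overlaps SNURF and has the same limit.

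UMIs were summed over all barcodes of a library and divided by the library total to give counts per 1000000 UMIs (CPM). A log2 ratio is log2 of the later CPM plus a pseudocount of 1 over the earlier CPM plus 1, so it understates differences of low genes. Folds in the text are ratios of CPM without a pseudocount. Each group has 1 library and cells are not replicates. There was therefore no test and no p-value, and no difference has a replicate check. Sums carry exact Poisson intervals, ratios exact conditional intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Totals were 124420771 to 172298619 UMIs per library. The widest CPM interval of a gene named by the rule below was ±2.49% in its higher library, and 3 UMIs correspond to 0.0174 to 0.0241 CPM. A gene was tested if its mean over the 4 libraries was at least 5 CPM (10460 genes) and called higher or lower by size alone, at 2-fold on the log2 scale.

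The contrasts were day 3 against day 2, day 5 against day 3 and day 10 against day 5, with day 10 against day 2 for counts and lists. Every contrast differs in day, and those of nCT against nTE also in medium and in the sort, so these cannot be separated. Before the data were examined, the contrasts, 37 gene lists with 511 entries, 26 anchor genes, the rule for genes named in the text and most alternatives were fixed. The cell type lists were naive and primed pluripotency, 8-cell-like, pan-trophoblast, trophectoderm, cytotrophoblast, syncytiotrophoblast, extravillous trophoblast, amnion, hypoblast, mesoderm, neuroectoderm and fibroblast. The other lists were targets of WNT, ERK, NODAL and TGF-beta, BMP, JAK-STAT, YAP-TEAD and p53, the DNA methylation machinery, imprinted genes, endogenous retrovirus-derived genes, glycolysis, hypoxia, cholesterol synthesis, oxidative phosphorylation, S phase, G2/M phase, interferon response, class I antigen presentation, dissociation stress, ATF4 stress response, epithelial junctions, integrins and laminins, ion and water transport, and nutrient transporters. A list median is the median log2 ratio of its tested members, given where at least 3 were tested, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Some genes stand in more than 1 list.

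Genes named per contrast are the 12 highest and 12 lowest by log2 ratio among genes with a mean of at least 25 CPM over both libraries. Mitochondrial, ribosomal protein, clone-named and LINC genes, XIST and Y-linked genes were left out. The anchor genes and a few members of each list with large ratios are also named.

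For clustering, barcodes with at least 1000 genes and at most 20% mitochondrial UMIs were kept (11921). Counts were scaled to 10000 per cell and log-transformed, 2000 highly variable genes and 30 principal components were used with 15 exact neighbours, and cells were grouped by the Leiden method at resolution 0.5. Clusters were ranked by number of cells. A cluster was called "like" a cell type when no other list had more markers among its top 10 genes by fold, at least 1 marker stood there, and at least 3 and at least 50% of the tested markers were 2-fold higher than in the other cells. Ties went to the list with the higher median. Cells outside the 5 clusters so named served as an alternative. This rule for naming clusters was set after the clusters were seen. Doublets were scored per library with the Scrublet method in scanpy and not removed. The caller marked 3, 1, 2 and 5 cells, from 0.0209% to 0.237% of a library, and so did not work here. An alternative without the 5% of barcodes with the most UMIs took its place. For shares of cells with a UMI of a gene, kept cells were thinned to 10000 UMIs each and shallower cells were left out (130, 162, 38 and 84 in order of day).

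Alternatives were median-of-ratios and trimmed-mean (TMM) scaling, totals without mitochondrial and ribosomal protein genes, cells weighted equally, other barcode filters, other pseudocounts, other expression filters, a 4-fold threshold and other clustering settings. The procedures were tested on simulated data. In a simulation of day 3 against day 2 over 10460 genes, the 2-fold call found 50 of 50 genes simulated 4-fold higher, 49 of 50 set to 0.25, 49 of 50 at 3-fold, 47 of 50 at 0.333 and 0 of 10260 unchanged genes. The 95% ratio interval held the true value for 94.7% of these genes. Both simulated libraries were drawn with Poisson counting error only. These results therefore do not show how often unreplicated libraries differ for other reasons. In a simulation from day-5 cells over 36601 features, 300 cells against 300 with 200 genes 3-fold apart gave 2 clusters, with 99.5% of cells placed with their own population, and cells with no difference gave 1 cluster. Within a population these cells varied by depth and counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.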

Results

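UMI counts, given below in counts per 1000000 UMIs (CPM), were obtained from 4 libraries, 1 for each of days 2, 3, 5 and 10 of a conversion of naive H9 cells to trophectoderm-like (nTE) and then cytotrophoblast-like (nCT) cultures. The libraries held 140408772, 172298619, 169099285 and 124420771 UMIs in order of day. Median UMIs per barcode were 62555, 31829, 46076 and 36697, and median genes per barcode were 7750, 6088, 7144 and 5592. The labels state mean reads per cell of 56312 to 130971 and median genes of 5500 to 8000. Mitochondrial genes took 5.44%, 5.56%, 9.54% and 10.2% of UMIs. Barcodes outside the clustering filters made up 13.96%, 6.99%, 15.7% and 32.1% of the libraries, and those kept held at least 91.6% of the UMIs of each library. With 1 library per day, the differences below are between libraries, and their intervals cover counting error only.

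The first question was how naive cells pass from pluripotency through trophectoderm to cytotrophoblast, as read from the anchor genes. POU5F1, a core pluripotency factor (chromosome 6, 31164337 to 31180731, minus strand), was at 336 CPM on day 2, 59.9 on day 3, 0.0828 on day 5 and 0.137 on day 10. CDX2, a trophectoderm factor (chromosome 13, 27962137 to 27971139, minus strand), stood at 26.4, 7.30, 0.0591 and 0.0161 CPM. HAND1, a factor of trophectoderm and mesoderm (chromosome 5, 154474972 to 154478264, minus strand), had 299, 156, 2.58 and 0.249 CPM. DNMT3L, a cofactor of de novo DNA methylation, went with them at 267, 92.9, 4.94 and 0.225 CPM. The trophoblast factors GATA2, GATA3 and TFAP2C were present on all 4 days, with GATA3 at 363, 567, 417 and 609 CPM, GATA2 at 218 to 307 CPM and TFAP2C at 104 to 135 CPM. TFAP2A was at 53.4, 52.4, 68.7 and 172 CPM.

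ENPEP, an aminopeptidase used as a sorting marker, was at 33.1, 51.9, 85.8 and 184 CPM in order of day. TACSTD2, the other sorting marker, was at 56.0, 56.2, 15.1 and 72.3 CPM. Since both genes encode proteins used in the sorts, their levels were in part set by the sorts. KRT7, a trophoblast keratin, was highest on day 5 (12.4, 65.1, 276 and 82.6 CPM), as was NR2F2 (44.9, 169, 179 and 83.4 CPM). Cytotrophoblast genes PAGE4 and ELF5 stood at 0.0570 and 0.363 CPM on day 2 and at 71.8 and 6.57 CPM on day 5, followed by 61.6 and 12.3 CPM on day 10. ITGA6, a laminin receptor subunit, had 31.9, 41.9, 109 and 116 CPM, while TP63, a cytotrophoblast factor, had 41.6, 32.4, 14.9 and 35.9 CPM. VTCN1 and ISL1, used as amnion markers, were at 18.6 and 2.13 CPM on day 2 and at 0.0964 and 0.0402 CPM on day 10.

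**Figure D1:**
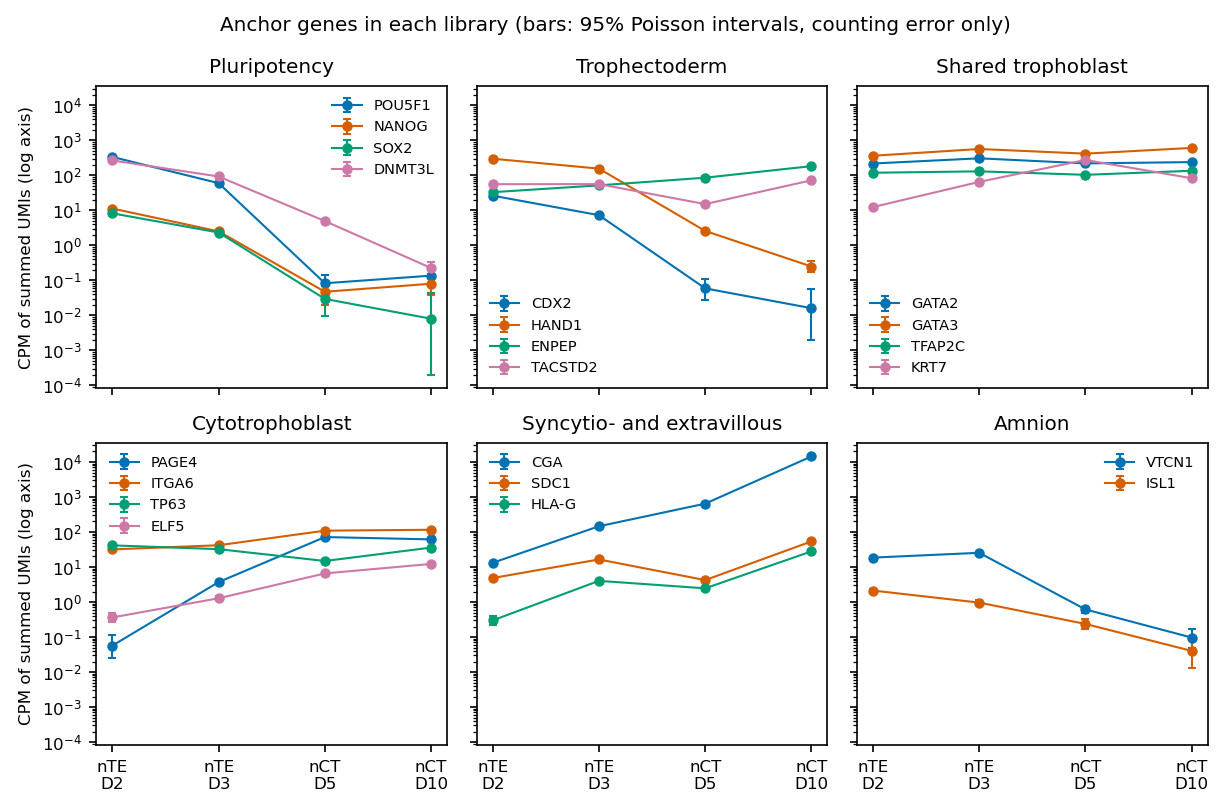
CPM of anchor genes (vertical log axis) against the libraries of days 2, 3, 5 and 10, with exact 95% Poisson intervals that cover counting error only. POU5F1 lies at 336 CPM on day 2 and 0.0828 CPM on day 5, and CGA at 13.2 CPM on day 2 and 14439 CPM on day 10.

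In cells thinned to 10000 UMIs, POU5F1 had a UMI in 82.4% (interval 80.6 to 84.0%) of 1916 cells on day 2 and in 25.03% (23.8 to 26.3%) of 4626 cells on day 3. On days 5 and 10 its shares were 0.0681% and 0.0986%. Without thinning, these shares were 93.3%, 45.4%, 0.303% and 0.379%. The naive anchor gene DPPA3 had a UMI in 90.3%, 87.9%, 50.1% and 56.2% of thinned cells in order of day, so not every naive gene was lost. KLF17, also a naive anchor gene, was rare throughout, at 0.365%, 0.108%, 0.0340% and 0%. CDX2 was found in 20.9%, 6.57%, 0% and 0% of thinned cells, where the exact intervals reach 0.126% on day 5 and 0.182% on day 10, limits for thinned cells with a UMI and not for cells that express it. Its shares without thinning were 52.4%, 15.3%, 0.202% and 0%. ENPEP had a UMI in 23.0%, 34.2%, 49.6% and 65.9% of thinned cells in order of day (57.2%, 61.0%, 87.7% and 87.8% unthinned). It was also in 10.9% of the naive-like cells described below, which were taken as its background. These cells are of days 2 and 3 and give no background for days 5 and 10. GATA3 was in 46.5% of them, so they may not lack ENPEP fully. Median depths before thinning were 69943.5, 33483.5, 50718 and 52530 UMIs for the libraries.

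Day 3 was compared with day 2 to describe the cells within the trophectoderm medium after BMP4 was withdrawn. On day 3, 6 of 10 naive pluripotency genes and 6 of 9 targets of BMP signalling were at least 2-fold lower, while 5 of 12 syncytiotrophoblast genes were higher. CCBE1, a secreted regulator of lymphatic growth (ENSG00000183287, chromosome 18, 59430939 to 59697662, minus strand), was 17.5-fold higher (interval 16.0 to 19.1). CGA, the alpha subunit of chorionic gonadotropin (ENSG00000135346, chromosome 6, 87085498 to 87095406, minus strand), was 11.05-fold higher (10.5 to 11.6). ID1, a BMP-induced inhibitor of helix-loop-helix factors (ENSG00000125968, chromosome 20, 31605283 to 31606515, plus strand), was 15.5-fold lower (15.04 to 16.1), and POU5F1 (ENSG00000204531) was 5.61-fold lower (5.49 to 5.73). In all, 338 of 10460 genes were at least 2-fold higher and 245 at least 2-fold lower.

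Among the genes with the highest ratios were also XAGE2 (14.7-fold), the imprinted noncoding RNA H19 (10.2-fold), the splicing factor MBNL2 (10.1-fold), the Notch coactivator MAML2 (9.94-fold), the adaptor FYB1 (9.92-fold) and CCKBR, a receptor of gastrin and cholecystokinin (9.64-fold). LGALS16, a placental galectin, was 8.35-fold higher, LGALS3 7.78-fold, the adhesion molecule CLMP 7.67-fold and HSD17B1, which makes estradiol, 6.11-fold. The genes with the lowest ratios were, after ID1, the tight junction gene CLDN10 (12.1-fold lower), PCAT14 (8.70-fold), SCGB3A2 (6.75-fold) and ID3 (6.28-fold). Those from GALNT17, FAM155A, PLPP1 and the prostaglandin-degrading HPGD to the peptide ligand APELA and the proton pump subunit ATP6V0D2 were 4.70-fold to 5.57-fold lower.

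The naive pluripotency list had a median log2 ratio of -1.33, with 6 of 10 tested members at least 2-fold lower and 0 higher (percentile 0 of matched lists). POU5F1, DPPA5 (234 and 56.5 CPM) and TDGF1 (20.7 and 5.51 CPM) were among them. NANOG and SOX2 were 4.49-fold and 3.53-fold lower over all barcodes, at log2 ratios of -1.81 and -1.47. Over cells outside the named clusters their log2 ratios were -0.67 and -0.27. The pseudocount of 1 makes log2 ratios of such low genes smaller than their folds, so a fall in these cells may be understated. BMP targets had a median of -1.19, with 6 of 9 lower and 0 higher (percentile 0), and ID1, ID3 and ID4 (40.3 and 6.74 CPM) had the largest differences. That median was -0.90 with a pseudocount of 5. Targets of NODAL and TGF-beta, with SMAD7 and SKIL lower, had a median of -1.04 over 3 members, which was -0.97 under median-of-ratios scaling, -0.96 under TMM, -0.87 with a pseudocount of 5 and -0.08 without the expression filter. The hypoblast list had a median of 1.24 over 4 members, from the basement membrane genes COL4A1 (6.89 and 24.3 CPM) and COL4A2 (18.8 and 77.2 CPM), while GATA6 had a log2 ratio of -0.54. Without the expression filter that median was -0.006.

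Lists of the trophoblast lineages had medians below 2-fold. The pan-trophoblast list was at 0.45 (2 of 12 higher, KRT7 and KRT19), the trophectoderm list at -0.12 (2 higher and 3 lower of 12), the cytotrophoblast list at 0.39 (5 higher and 1 lower of 17) and the syncytiotrophoblast list at 0.63 (5 of 12 higher). The syncytiotrophoblast members were HSD3B1, which makes progesterone (0.534 and 43.9 CPM), CGA, ERVFRD-1, SDC1 and GCM1. When each cell had equal weight, the log2 ratio of CGA was 0.95 in place of 3.37, and over cells outside the named clusters that of SDC1 was 0.68 in place of 1.58. Between cluster 2 of day 3 and cluster 3 of day 2, the largest of each library, the median of this list was 0.04 (4 higher and 1 lower of 12). Endogenous retrovirus-derived genes had 4 of 9 members higher at a median of 0.41, among them the fusogen ERVFRD-1 and ERVV-2. The extravillous list stood at 0.63 (2 higher, 1 lower of 8). Cholesterol synthesis genes had a median of 0.38, with 0 of 18 at least 2-fold apart and percentile 100. YAP-TEAD targets were at 0.45, the G2/M list at -0.34, the DNA methylation machinery at -0.61 with DNMT3L lower, and JAK-STAT targets, whose pathway was inhibited in both libraries, at -0.22 with 0 of 8 apart.

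Day 5 was compared with day 3 to describe the step from trophectoderm to cytotrophoblast culture. Of the ERK targets 7 of 10 were at least 2-fold higher on day 5, and 8 of 10 naive pluripotency and 6 of 12 trophectoderm genes were lower. PEG10, an imprinted gene of retrotransposon origin needed for placenta formation (ENSG00000242265, chromosome 7, 94656325 to 94669695, plus strand), was 52.4-fold higher (50.6 to 54.3), at 965 CPM. B2M, the light chain of class I molecules, was 18.1-fold higher (17.1 to 19.1), and PAGE4 19.3-fold (17.8 to 20.9). HAND1 (ENSG00000113196) was 60.4-fold lower (54.9 to 66.5), and POU5F1 was 724-fold lower (431 to 1325). In all, 587 genes were at least 2-fold higher and 671 at least 2-fold lower.

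The secreted chaperone CLU was 54.0-fold higher, the potassium channel KCNN4 51.7-fold and the fatty acid transporter SLC27A2 48.3-fold. ARID5B followed at 31.6-fold, the kinase PRKG1 at 27.0-fold, the oxidase CYP1B1 at 25.7-fold, the fibrillin FBN2 at 25.3-fold, the caveolar CAV1 at 19.8-fold and the imprinted PEG3 at 16.4-fold. The genes with the lowest ratios were POU5F1, DPPA5 (735-fold lower), MARCKS (151-fold), the alkaline phosphatase ALPG (121-fold), the sodium-chloride transporter SLC12A3 (62.5-fold), HAND1 and KHDC1L (51.8-fold). GAS7, the water channel AQP3, IQGAP2, S100A6 and the tubulin TUBA1A were 23.1-fold to 43.6-fold lower.

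The naive list had a median of -2.45 (8 of 10 lower, 0 higher, percentile 0) and the trophectoderm list one of -1.03 (6 of 12 lower, 0 higher, percentile 0), with HAND1, FABP3 (18.9 and 1.16 CPM) and CDX2 at the low end. The trophectoderm median was -0.87 with a pseudocount of 5 and -0.36 over genes of at least 20 CPM. ERK targets had a median of 1.30 (7 of 10 higher, 0 lower, percentile 100), with FOSL1 (0.789 and 22.9 CPM), ETV5 (0.238 and 6.22 CPM) and the cyclin CCND1 (104 and 384 CPM) higher. That median was 0.98 with cells weighted equally, 0.996 with a pseudocount of 5 and 0.83 without the expression filter. The dissociation stress list, which shares EGR1 and IER3 with it, stood at 0.70 (4 of 13 higher), and mitochondrial UMIs at 9.54% against 5.56%. Targets of p53 had a median of 1.08 (6 of 11 higher, 0 lower, percentile 100), with TP53I3 (10.4 and 67.1 CPM), the cell cycle inhibitor CDKN1A (12.9 and 71.8 CPM) and RRM2B (14.3 and 45.9 CPM) higher. That median was 0.73 with cells weighted equally, 0.89 without the 5% of barcodes with the most UMIs, 0.98 with a pseudocount of 5 and 0.91 without the expression filter.

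Cytotrophoblast genes had a median of 0.55, with 6 of 17 higher (PEG10, SIGLEC6, PAGE4, ELF5, ITGA6 and VGLL1) and 2 lower (DUSP9 and TP63). The log2 ratio of TP63 was -0.96 with cells weighted equally and -0.91 with a pseudocount of 5, and that of ELF5 was 0.88 with this pseudocount. The imprinted list was at 0.67 (4 of 12 higher and 2 lower, percentile 100), with PEG10, PEG3, SGCE and PHLDA2 higher and the noncoding RNA MEG3 and SNRPN lower. WNT targets were at 0.66 (2 of 6 higher, 1 lower), with AXIN2 3.77-fold higher (3.54 to 4.01) and NOTUM also higher, and NKD2 lower. The pan-trophoblast list was at -0.44, with KRT7 and MSX2 higher and KRT8, KRT18, KRT19 and TACSTD2 lower. The S phase list stood at 0.48 (3 of 20 higher, percentile 99.96), the interferon list at 0.04 with IFI6 higher and IFITM1, IFITM2 and IFITM3 lower, and the ATF4 list at -0.36 (1 higher, 2 lower of 12). In the amnion list (median 0.44, 1 higher and 2 lower of 5), VTCN1 was 41.4-fold lower (34.1 to 50.8). Genes of ion and water transport were at 0.27, with AQP3 and SCNN1A lower and SLC12A2 higher of 9.

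Day 10 was compared with day 5 to describe longer culture in the cytotrophoblast medium. On day 10, 9 of 12 syncytiotrophoblast, all 12 hypoxia response and all 4 tested class I genes were at least 2-fold higher, and 11 of 20 G2/M genes were lower. CGA was 22.3-fold higher (22.2 to 22.5), at 14439 CPM. CLIC3, a chloride intracellular channel gene (ENSG00000169583, chromosome 9, 136994635 to 136996803, minus strand), was 72.9-fold higher (67.4 to 79.1). CCKBR (ENSG00000110148, chromosome 11, 6259736 to 6272127, plus strand) was 36.1-fold lower (34.2 to 38.2) and SNRPN, an imprinted small nuclear ribonucleoprotein gene (ENSG00000128739, chromosome 15, 24823637 to 24978723, plus strand), was 28.8-fold lower (25.2 to 33.1).

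Of the 10460 genes, 776 were at least 2-fold higher and 2096 lower, so 27.0% of both were higher. Under median-of-ratios scaling 1078 were higher and 1429 lower (43.0% higher), and TMM scaling gave 1076 and 1429 (43.0%). The median log2 ratio of all tested genes was -0.38, or -0.17 under either of these scalings. List medians for day 10 against day 5 are therefore also given relative to this median of -0.38.

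PSG3, a pregnancy-specific glycoprotein gene, had 6241 UMIs on day 10 and 5 on day 5, and S100A9, a calcium-binding protein gene, 6351 and 11. Other genes with the highest ratios were the collagen receptor subunit ITGA2 (40.4-fold), the protease inhibitor SERPINE1 (38.4-fold), ECM1 (34.8-fold), CGB3, a beta subunit of chorionic gonadotropin (32.8-fold), the creatine transporter SLC6A8 (7.16 and 229 CPM), the coagulation inhibitor TFPI (28.8-fold), TMEM40 (26.0-fold) and LGALS1 (25.8-fold). After CCKBR and SNRPN, the genes with the lowest ratios were NECTIN1 (15.9-fold lower), the fatty acid binding proteins FABP5 (15.1-fold) and FABP7 (14.6-fold), TIMP4 (13.1-fold), USP27X (11.8-fold), FRAS1 (11.5-fold) and the chaperone HSPA8 (11.3-fold). DANCR, PLXDC2 and SYNE1 were 9.74-fold, 9.44-fold and 8.92-fold lower.

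The syncytiotrophoblast list had a median of 2.77, or 3.15 relative to all tested genes, with 9 of 12 higher and 0 lower (percentile 100). Besides CGA, CGB3 and PSG3, INSL4 (3.27 and 81.2 CPM) and SDC1 (12.7-fold, 11.8 to 13.8) were higher. Over cells outside the named clusters that median was 0.22, and the log2 ratios of CGA and SDC1 were 0.24 and 0.69. The day-5 cells in that comparison include the unnamed cluster 9, described below, in which CGA was at 8037 CPM. Between cluster 4 of day 10 and cluster 1 of day 5, the largest of each library, the list median was 1.34, with 7 of 12 higher and 0 lower. RNA of these genes free in the day-10 cell suspension may add to that median, which was not tested. All 12 hypoxia response genes were higher (median 2.14, or 2.52 relative, percentile 100), including NDRG1 (0.325 and 13.3 CPM), ANKRD37 (5.79 and 63.4 CPM) and INSIG2 (11.7 and 78.5 CPM). Glycolysis genes had a median of 0.75 (1.13 relative, 7 of 17 higher, 0 lower), with ALDOC and ENO2 at the high end. The 4 class I genes HLA-C, HLA-E, B2M (143 and 505 CPM) and TAPBP were all higher (median 1.37, or 1.75 relative), and the median was 0.61 without the expression filter. Dissociation stress genes had a median of 1.32 (1.70 relative, 9 of 13 higher, 0 lower), with ATF3 at 29.4 and 141 CPM, in the library where 32.1% of barcodes failed the filters.

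Extravillous genes had a median of 1.21 (1.59 relative, 5 of 8 higher, 2 lower), with HLA-G, a class I molecule of invading trophoblast, 11.4-fold higher (10.3 to 12.6), TIMP3 and ITGA5 also higher, and NOTUM and ITGA1 lower. That median was 0.71 with a pseudocount of 5 and 0.11 without the expression filter. The G2/M list had a median of -1.01 (-0.63 relative, 11 of 20 lower, 0 higher, percentile 0.07), with CENPE, PLK1 and MKI67 (91.0 and 30.1 CPM) lower. It was -0.79 under both other scalings and over cells outside the named clusters, -0.91 without mitochondrial and ribosomal protein genes and -0.92 with a pseudocount of 5. S phase genes were at -0.75 (-0.37 relative, 7 of 20 lower) and oxidative phosphorylation genes at -0.78 (-0.39 relative, 5 of 21 lower, 0 higher), with NDUFB9 and CYCS lower. ERK targets were at 0.90 (1.28 relative), and at 1.12 under median-of-ratios scaling (5 of 10 higher, with ETV4 at 4.54 and 48.6 CPM, and CCND1 lower). Interferon genes were at 0.84 (1.22 relative), and at 1.07 under that scaling (3 of 7 higher, with ISG15 at 30.7 and 112 CPM, and IFITM2 lower).

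JAK-STAT targets had a median of 0.65 (1.03 relative, 2 of 8 higher, IRF1 and JUNB), nutrient transporters one of 0.75 (1.14 relative, 6 of 12 higher, SLC16A3 at 15.2 and 256 CPM, LRP2 lower) and epithelial junction genes one of 0.20 (0.59 relative, CLDN3 and DSP higher of 16). The naive list was at 0.21 (0.60 relative, 3 higher and 1 lower of 10, percentile 97.8). The pan-trophoblast list was at 0.57 (0.95 relative), with TFAP2A, KRT8, KRT18 and TACSTD2 higher and KRT7 3.34-fold lower (3.27 to 3.41). The cytotrophoblast list was at 0.09 (0.47 relative, 6 higher and 2 lower of 17), with EGFR, the receptor of the EGF in the medium, at 41.2 and 307 CPM, SIGLEC6 and TP63 higher, and CCKBR and PEG10 lower.

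Between day 10 and day 2, 1325 genes were at least 2-fold higher and 2599 lower (33.8% higher), or 1834 and 1647 (52.7%) under median-of-ratios scaling and 1790 and 1695 (51.4%) under TMM. Syncytiotrophoblast (3.14, 10 of 12 higher, 1 lower), endogenous retrovirus-derived (2.88, 6 of 9 higher, 1 lower), extravillous (2.74, 5 of 8 higher, 1 lower), ERK (2.67, 8 of 10 higher, 1 lower) and class I (2.03, 3 of 4 higher) lists had the highest medians, against -0.37 for all tested genes. The cytotrophoblast list was at 1.83 (10 of 17 higher, 3 lower), with PAGE4 at 0.0570 and 61.6 CPM. Hypoxia (1.75), dissociation stress (1.64), integrins and laminins (1.52), imprinted genes (1.42) and glycolysis (1.29) followed. The medians of the naive list (-2.25, 9 of 10 lower), the DNA methylation machinery (-1.65, 5 of 8 lower, 1 higher), the G2/M list (-1.18) and BMP targets (-1.01) were the lowest. The medians of several of these lists came within 2-fold under 1 or more alternatives. Among these were 0.50 for dissociation stress with cells weighted equally, 0.02, 0.52 and 0.73 for extravillous, imprinted and class I genes without the expression filter, -0.10 for integrins and laminins and 0.39 for BMP targets over genes of at least 20 CPM, and -0.85 for the G2/M list and -0.70 for BMP targets under median-of-ratios scaling. The order of the highest lists also depended on the cells used. Between cluster 4 of day 10 and cluster 3 of day 2, syncytiotrophoblast and retrovirus-derived genes were at 1.61 and 1.51. These lay below ERK (3.15), extravillous (2.96), class I (2.23) and cytotrophoblast (2.06) genes. RNA free in the day-10 cell suspension may add to the values of cluster 4, which was not tested.

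**Figure D2:**
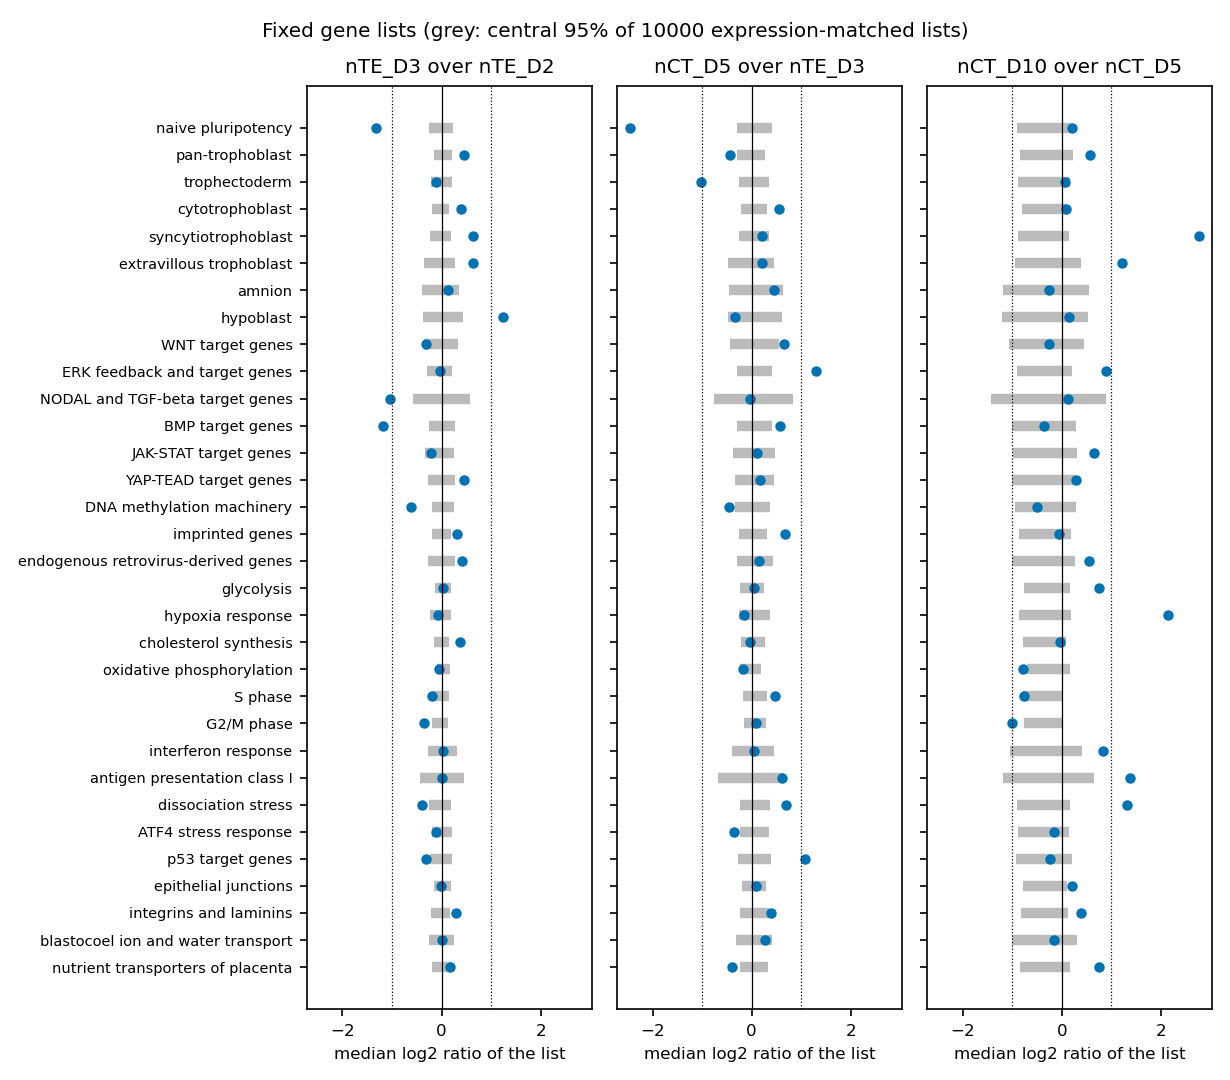
Median log2 ratio of each gene list with at least 3 tested members, for day 3 against day 2, day 5 against day 3 and day 10 against day 5, with the central 95% of 10000 matched random lists in grey. The hypoxia list lies at -0.08, -0.15 and 2.14, and the naive pluripotency list at -1.33, -2.45 and 0.21.

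Lists with fewer than 3 tested members have no median. CD24 of the primed list was at 422, 272, 120 and 238 CPM in order of day, and ROR2 of the mesoderm list at 8.28, 9.79, 75.3 and 47.8 CPM. KHDC1L of the 8-cell-like list was at 871, 214, 4.13 and 1.33 CPM, and COL1A1 of the fibroblast list at 13.1, 5.11, 6.14 and 5.38 CPM. The neuroectoderm list had 0 tested members.

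Clustering of 11921 cells gave 11 clusters, and most were mainly of 1 library, so they may stand for that library rather than for a cell type. Cluster 1 held 93.7% of the kept cells of day 5, cluster 4 held 83.9% of those of day 10, cluster 3 held 73.5% of those of day 2 and 8.56% of those of day 3, and clusters 2 and 5 held 56.8% and 23.1% of those of day 3. These 5 stayed unnamed. The cluster naming rule, which was set after the data were seen, kept clusters 1 and 4 out of the cytotrophoblast class (4 and 6 of 16 markers higher) and cluster 3 out of the trophectoderm class (5 of 12). Cluster 4 also had 4 of 8 extravillous markers higher and cluster 3 had 5 of 10 naive pluripotency markers, with 0 of either among their top 10 genes. Cluster 9, with 6.05% of day-5 cells, also stayed unnamed, with 9 of 12 syncytiotrophoblast markers higher and 3 of 11 trophectoderm markers.

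Naive-like cells (cluster 7, led by DPPA5, TDGF1, NANOG and FGF4) made up 13.3% of day-2 cells (interval 11.9 to 14.8%) and 3.26% of day-3 cells (2.77 to 3.80%), in libraries sorted for TACSTD2. At Leiden resolution 0.3 these shares were 90.03% and 11.6%, and with each library clustered alone 10.9% and 11.4%, so neither their size nor their order held under every setting. None were found among 2975 day-5 or 2112 day-10 cells, where the intervals reach 0.124% and 0.175%. In cluster 7, 13 of 15 tested naive markers were at least 2-fold higher, but not every marker went with the name. Among thinned cells, KLF17 had a UMI in 1.24% of cluster 7, and DPPA3 in 73.4%, against 92.2% in cluster 3. The trophoblast factors GATA3 and HAND1 had one in 46.5% and 21.4% of cluster 7, against 90.5% and 77.2% in cluster 3. Syncytiotrophoblast-like cells were 5.23% of day 2 (4.31 to 6.28%) and 7.64% of day 3 (6.91 to 8.43%), mainly in cluster 6, which was led by ERVFRD-1, CYP19A1 and OVOL1. At resolution 1.0 they were 0.342% and 3.15%. On day 5 they were 0.168% (0.0546 to 0.392%), and on day 10 they were 15.8% (14.3 to 17.4%), in cluster 8, which was led by CGA, PSG3, INSL4 and CGB3. The class thus rests on different clusters in nTE and nCT libraries. The day-5 share leaves out cluster 9 (6.05% of day-5 cells), which had 0 syncytiotrophoblast markers among its top 10 genes. Cluster 9 had 9 of 12 of these markers higher at a median log2 ratio of 1.34, against 6 of 12 at 0.79 in cluster 6. The low day-5 share therefore depends on the naming rule. In cluster 8 CGA was at 72284 CPM, and in cluster 4 of the same library at 732 CPM. Of thinned cells in cluster 4, 98.8% had a CGA UMI, against 100% in cluster 8 and 2.49% in the naive-like cells. The naive-like cells are of days 2 and 3 and give no background for day 10. Free CGA RNA in the day-10 suspension therefore remains open. SDC1 was in 6.71% of cluster 4 and 77.7% of cluster 8.

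An 8-cell-like cluster, led by ZSCAN4 among others, made up 3.42% of day-2 cells (2.68 to 4.30%) and 0.292% of day-3 cells (0.160 to 0.490%), with a median of 5615 UMIs, which was 8.32% of that of its own library. No cluster met that name at resolution 0.3, with the stricter barcode filter or without S and G2/M phase genes. A fibroblast-like cluster, led by VIM, COL1A2, COL3A1 and COL1A1, made up 2.15% (1.57 to 2.88%) and 0.251% (0.130 to 0.437%) of these libraries, with a median of 4360 UMIs. With at least 3000 genes required, the fibroblast-like share was 0% on day 2.

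**Figure D3:**
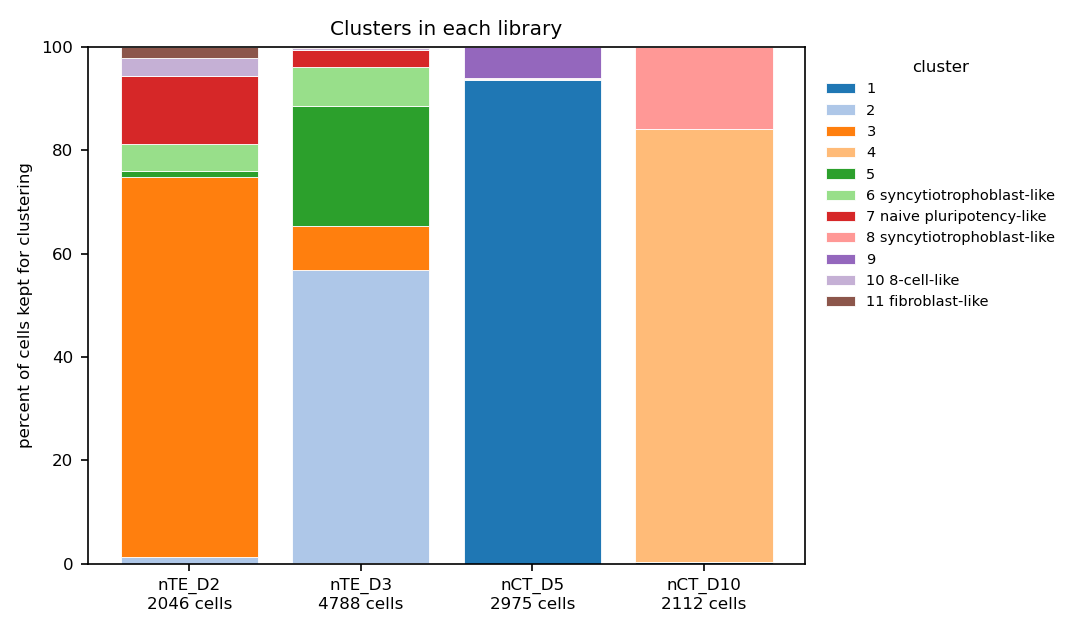
Share of the kept cells of each library (percent) in each of the 11 clusters, as stacked bars. Naive-like cells lie at 13.3% on day 2 and 3.26% on day 3, and syncytiotrophoblast-like cells at 15.8% on day 10.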

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

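Alternatives based on cells kept for clustering, on cells outside the named clusters and on barcodes without the 5% with the most UMIs were chosen after the data were seen, as were the measures that sum up cluster names and anchor shares. Of 126 contrasts of named and anchor genes that were at least 2-fold apart, 0 to 13 came within 2-fold under any 1 alternative, and 1 changed direction. That was SDC1 on day 5 against day 3, with log2 -1.74 over all barcodes and 0.28 over cells outside the named clusters. The day-5 cells in that comparison include the unnamed cluster 9, where 16.2% of thinned cells had an SDC1 UMI. That share was 0.975% in cluster 1 of day 5, and 3.23% and 1.86% in clusters 2 and 5, mainly of day 3. Of 29 list medians at least 2-fold apart, 0 to 9 came within 2-fold under an alternative, and 0 to 6 others reached it. The hypoblast list of day 3 against day 2 changed sign without the expression filter (-0.00603). Over genes of at least 20 CPM, BMP targets (0.39) and integrins and laminins (-0.10) of day 10 against day 2 changed sign. Both filters change which members are tested, which accounts for these 3.

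Counts of genes at least 2-fold apart depended on scaling for day 10 against day 2, where 1647 were lower under median-of-ratios and 1695 under TMM scaling. With a pseudocount of 5, 181 were higher on day 3 than day 2, 390 higher on day 5 than day 3 and 1360 lower on day 10 than day 5. Without the expression filter, 457 were lower on day 3 than day 2, 1076 lower on day 5 than day 3, 1311 higher on day 10 than day 5 and 2119 higher on day 10 than day 2. Over genes of at least 20 CPM, fewer genes were tested, with 202 higher and 102 lower on day 3 than day 2, 304 and 342 on day 5 than day 3, 414 and 1287 on day 10 than day 5, and 748 and 1541 on day 10 than day 2. At a 4-fold threshold these pairs were 59 and 27, 147 and 208, 210 and 230, and 534 and 629.

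The naive-like share of day 2 (13.3%) was 90.03% at Leiden resolution 0.3, 11.1% with 15 principal components, 17.0% without S and G2/M genes and 10.9% with each library clustered alone. On day 3 (3.26%) it was 11.6% at resolution 0.3 and 11.4% with libraries alone. The 8-cell-like share of day 2 (3.42%) was 5.03% with 4000 variable genes and 0% at resolution 0.3, with at least 3000 genes and at most 10% mitochondrial UMIs, or without S and G2/M genes. Syncytiotrophoblast-like shares were 0.342% on day 2 and 3.15% on day 3 at resolution 1.0, 4.2% on day 2 with 15 components, 6.77% on day 3 with libraries alone and 12.9% on day 10 with the stricter barcode filter. That filter removed the fibroblast-like cells of day 2 (0%), which have few genes. There were 18 clusters at resolution 1.0 and 35, summed over libraries, with each clustered alone, against 11. An anchor gene had a UMI in at least 50% of the cells of a library in 29 cases, in 48 without thinning, in 18 at 5000 UMIs and in 15 when 2 UMIs were required, since each of these settings changes the depth or the bar. The cause of the other differences was not tested. Depth limits genes near 3 UMIs per library, such as NANOG, SOX2 and CDX2 on days 5 and 10. No paired analysis was possible because each group has 1 library.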

Other observations

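The chaperone, chaperonin, chromosome 15 and chromosome 14 gene lists in this part were written after the values of HSPA8, SNRPN and MEG3 were seen, and all tests were chosen after the patterns were seen. For the long noncoding RNA test of another species and the SNRPN test of a minority of cells, the deciding values had not been seen when the tests were written.

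Most members of a list of chaperones, mainly cytosolic and mitochondrial, were lower on day 10 than on day 5. The list leaves out HSPA1A, HSPA1B, HSPB1 and DNAJB1. These stand in the dissociation stress list, where 9 of 13 tested members were higher and 0 lower. Of 12 chaperones 9 were at least 2-fold lower, with a median log2 ratio of -1.46, against -0.38 for all tested genes (percentile 0 of matched lists, whose central 95% ran from -0.82 to 0.28). This list holds HSPA8, which prompted it, so its place among matched lists gives no separate support. HSPA8, the constitutive HSP70 (chromosome 11, 123057489 to 123063230, minus strand), was at 1374 and 122 CPM, HSPH1 at 157 and 24.8 CPM, HSPD1 at 1186 and 313 CPM, and HSP90AA1 at 3490 and 1137 CPM. The endoplasmic reticulum chaperones HSPA5 and HSP90B1 were within 2-fold, with log2 ratios of 0.58 and 0.67, or -0.01 and 0.48 between the largest clusters. Of 8 subunits of the cytosolic chaperonin, 6 were lower (median -1.41, percentile 0.02), with CCT3 3.83-fold lower (interval 3.76 to 3.89). Between the largest clusters of the 2 days, the medians were -1.37 and -1.34. Both lists had medians of 0.01 on day 3 against day 2.

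The maternally expressed noncoding RNAs MEG3 and MEG8 of chromosome 14 were lower on the later days, as was POU5F1. MEG3 was at 145, 34.8, 0.106 and 0.121 CPM in order of day, and MEG8 at 147, 33.8, 0.544 and 0.281 CPM. On day 2, MEG3 was at 593 CPM in the naive-like cluster and 63.6 CPM in cluster 3. The imprinted H19 had the opposite order, at 42.9, 438, 719 and 1860 CPM.

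Cells of the fibroblast-like cluster held the collagen gene COL1A1 at 6925 CPM, against 2.43 CPM in the other kept cells of days 2 and 3, and mitochondrial genes took 0.248% of their UMIs against 5.13%. Droplets with only free RNA are argued against, since the median CPM of the pan-trophoblast genes was 18.99% of that in the other cells. Long noncoding RNAs other than MALAT1 and NEAT1 took 1.11% of UMIs against 2.10%, or 52.7% of the other cells' share, which lies between the bounds set for human cells and for cells of another species whose transcripts partly match the human reference. With 56 cells and no reads, these 2 sources cannot be told apart by this test. In this cluster the class I genes HLA-A, HLA-B, HLA-C and B2M had 1, 0, 1 and 5 UMIs, against 1755 for COL1A1. They were at 3.95, 0, 3.95 and 19.7 CPM there, and at 1.53, 0.490, 8.53 and 8.05 CPM in the other kept cells. These genes were thus low in both and do not separate the 2 sources. No test had been set for these genes. Fibroblast-like cells were present although both libraries were sorted for TACSTD2, and the sort does not tell the 2 sources apart. No biological explanation was tested.

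All 12 tested hypoxia response genes were higher on day 10 than on day 5, at a median log2 ratio of 2.14. Over cells outside the named clusters the median was 2.01, which argues against the larger syncytiotrophoblast-like share as the whole cause. It was 2.09 over barcodes with at least 3000 genes and at most 10% mitochondrial UMIs, so low-quality barcodes do not account for it either. Under median-of-ratios scaling the list median was 2.37. That scaling moved the median of all tested genes from -0.38 to -0.17, so it could only raise the list median and decides nothing about scaling. Longer or denser culture by day 10 is a biological hypothesis that may explain the higher hypoxia genes, and it was not tested, since day and library are the same here.

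SNRPN was 28.8-fold lower on day 10 than on day 5 and SNHG14, the host transcript on the same strand, 6.81-fold (6.44 to 7.21), against 2.31-fold for NDN (2.04 to 2.62, at 6.22 and 2.69 CPM), 1.46-fold for UBE3A and 1.42-fold for MKRN3, with MAGEL2 at 0.0591 and 0 CPM. The median of the 5 tested members of the chromosome 15 list was -0.97, within the -1.12 to 0.47 of matched lists, but it lay below theirs at -0.99 for day 5 against day 3 (-0.52 to 0.54) and at -1.43 for day 10 against day 2 (-1.36 to 0.70). Between the largest clusters it was -1.03 for day 5 against day 3 and -1.16 for day 10 against day 2, the latter inside that range. The list holds SNRPN, which prompted it, so its place among matched lists gives no separate support. For day 5 against day 3, SNHG14 and NDN were at -0.99 and -1.14, but MKRN3 and UBE3A at 0.13 and 0.49. For day 10 against day 2 they were at -3.86, -1.43, -0.39 and -0.29. A larger syncytiotrophoblast-like share is argued against by a log2 ratio of SNRPN of -4.05 between cluster 4 of day 10 and cluster 1 of day 5. SNRPN had a UMI in 8.24% of 1772 cells of cluster 4, at a mean of 1.36 UMIs in those cells. In cluster 1 it had one in 72.05% of 2787 cells, at 3.90. A Poisson interval of the UMI sum gives 1.17 to 1.56 for the mean of 1.36. This interval is only approximate, because these cells were chosen for having a UMI. The mean lies under the bound of 1.5 set beforehand, and its interval passes that bound but stays under 2. Day-5 levels in a minority, with no SNRPN in all other cells, would need at least 2 and are argued against to that extent. A smaller group of higher cells among low ones stays open, since even cells would give a mean of 1.06. Reads shared with the overlapping SNURF stay open, since SNURF was under 1 CPM in every library (0.0161 CPM on day 10) and reads that fit both genes may be counted for neither, as does any other difference between these 2 libraries, and no biological explanation was tested.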
